A study of Drosophila melanogaster with 8 samples.

How the data were processed

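RNA was measured in 8 libraries of adult Canton S flies, a standard wild-type strain of Drosophila melanogaster. Flies of each sex were kept for 7 days on 1 of 4 diets and were 15 days old at collection, after a final 2 h on standard food. The diets were a normal diet (ND), a high-fat diet (HFD), the high-fat diet with quercetin glucoside (HFD+QG) and the high-fat diet with epigallocatechin gallate (HFD+EGCG). Bodies without wings or legs were used. RNA was extracted with Isogen and libraries were made with a strand-specific SureSelect kit, per the labels' protocols. The doses of both compounds and the composition of the high-fat diet are not given in the labels used here. The labels give 1 library per diet and sex, and nothing in them says from how many flies or cultures a library was made, so p-values measure only the spread between libraries, which may be technical.

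The deposited values are FPKM (fragments scaled to transcript length and library size) for each FlyBase transcript, which the authors rounded to whole numbers, so that they were handled as a score with no counts behind it. CASAVA 1.8.2, TopHat2 2.1.1 and Cuffdiff 2.2.1 are named in the submitters' processing notes, without the parameters used. Neither a genome build nor any scaling between libraries is given in the sources used here, nor whether the tables of the sexes were made in the same run. Each table lists 34475 transcripts. Gene locations in the deposited annotation matched those of BDGP6.54 (Ensembl release 115) in start and end for 17286 of 17431 genes (99.2%), and coordinates are printed as the tables give them. Of the genes, 13835 carried a name in the tables. Of the other 3820, 3743 were named from the reference by their FlyBase identifier. Some names in the tables had been turned into dates by a spreadsheet, and 7 names of the fixed gene lists were not found.

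Transcript FPKM were summed per FlyBase gene identifier, which gave 17655 genes. Depth is unknown, because rounded FPKM keep no count of reads, and no interval for counting error can be given. A transcript listed at 0 stands for anything under 0.5 FPKM or for an estimate that failed. A gene listed at 0 can hold such an amount in each of its transcripts. Only 10191 genes had 1 transcript, and a gene had up to 75. For these reasons no fold is printed against a library listed at 0. Changes are differences of log2(FPKM + 1), a scale that understates the change of genes at low FPKM. On whole numbers a step from 0 to 1 FPKM still counts as 2-fold, so counts of 2-fold genes include such rounding steps. Genes that share sequence with close relatives, such as the amylase, maltase, Jonah protease and chorion families, are uncertain to the extent that the authors' software divided their reads.

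A total of 9848 genes, 9335 of them protein-coding, had an FPKM of at least 1 in 1 or more libraries of each sex and entered the comparisons across sexes. Within a sex, 13304 genes in males and 10254 in females were described. Because a diet has 1 library in each sex, 2 descriptions were used. First, genes at least 2-fold different in each sex were counted, with those different the same way in both sexes set beside those different in opposite ways and beside the number independent lists would share. Second, limma 3.58.1 in R 4.3.3 fitted an additive model of sex and diet to all 8 libraries, with a trended prior, 3 residual degrees of freedom, 2.27 prior degrees of freedom and Benjamini-Hochberg adjustment at 0.05. In that model a diet effect that differs between the sexes counts as error. All diets share the error estimate of a gene, so disagreement between the sexes on ND also enters the comparisons without ND. The sexes' diet profiles were compared by a one-sided exact permutation test over the 24 matchings of female to male diets, whose smallest possible p is 0.0417.

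The 29 gene lists (fat synthesis, lipolysis, beta-oxidation, digestive lipases, carbohydrases and serine proteases, immune effectors, Turandot and JAK-STAT genes, heat shock proteins, P450s, glutathione S-transferases and UGTs, antioxidant and metal-binding proteins, insulin and TOR signalling, hormones, sugar metabolism, fat body proteins, clock genes, the respiratory chain, the proteasome, ribosomal proteins, and markers of egg, germline, accessory gland, testis, muscle, neurons, haemocytes, cuticle and gut structure) were described by the percentile of their median change among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart when it lay under 2.5 or over 97.5 in the same direction in both sexes. These percentiles describe the libraries and are not p-values. Members passing limma were counted over all genes and adjusted over the list alone, without a further correction for the number of lists.

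The samples' groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each comparison with ND or HFD, the 10 highest and 10 lowest genes by the smaller of the male and female changes among genes changed the same way, the 5 highest and 5 lowest in each sex, any genes passing limma, and the 2 to 4 most changed members of each list described, at an FPKM of at least 5. QG against EGCG took 5 in each direction. Small noncoding RNAs that the rule took are given as numbers. Yolk protein and vitelline membrane genes, Amy-p, PPO1, DptB, ACC and AcCoAS in the ND comparison, lush, Obp69a, Obp19d, antdh and Lip3, and the overlapping and flanking genes beside Cyp4g1 were named outside that rule, after their values were seen.

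The steps were tested on simulated data for HFD against ND with 200 of 9848 genes changed. The size rule counted 99.0% of genes changed by a log2 of 3 and 88.0% of those changed by 1.5, with 60 unchanged genes. limma passed 89% and 77% of these, with 169 genes passing in all and 3 of them unchanged. The simulated change was identical in both sexes and the noise level was shared within an expression bin. In the real libraries disagreement between the sexes on a diet counts as error. These shares therefore do not measure the power of either rule there. The matching test gave an exact permutation p of 0.2083 on these simulated effects. The simulated change was the same in the 3 high-fat diets, which the test then cannot tell apart. This p therefore does not measure its power. Of 100 random lists 7 fell outside the percentile bounds, and 50 of 50 shifted lists did. Alternatives were a pseudocount of 0.1 or 5, an FPKM minimum of 10 or any value above 0 (which keeps the same genes, since FPKM are whole numbers), FPKM rescaled to a common sum per library, median-centring within a sex, a 1.5-fold rule, limma without a trend and without each library in turn. Chosen after the data were seen were leaving out genes listed at 0, noncoding genes, genes annotated to peak in early embryos or adult females, and the egg, germline, accessory gland and testis lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.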

Results

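The series asked how a high-fat diet, and the plant polyphenols quercetin glucoside (QG) and epigallocatechin gallate (EGCG) added to it, act on gene expression in a fly model of diet-driven obesity. QG is a flavonol bound to glucose and EGCG is the main catechin of green tea. Whole-body RNA without wings or legs was measured in males and females on ND, HFD, HFD+QG and HFD+EGCG, with 1 library for each of the 8 groups, so a difference within a sex has no replicate check. Summed FPKM per library lay between 885956 and 1000513. Males had 12758 to 12892 genes listed above 0 and females 9473 to 9844. The sex labels matched the marker genes in every library. The yolk protein gene Yp1 was listed at 0 in the 4 male libraries and at 2385 to 7367 FPKM in the 4 female ones, and the accessory gland gene Mst57Db was at 27482 to 39016 FPKM in males and at 0 or 1 in females. ND stood apart from the 3 high-fat libraries in females, with root mean square log2 distances of 0.64 to 0.72 to them against 0.30 to 0.32 among them. In males the corresponding distances were 0.47 to 0.49 and 0.36 to 0.42. Both male ranges are raised by abundant genes listed at 0 in some male libraries only, such as mt:CoI and Cyp4g1. The distances were not computed without these genes, so the sexes cannot be compared closely by them.

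The first question was what the high-fat diet changed. In both sexes, genes of sugar and starch digestion were lower on HFD than on ND, and nuclear genes of the mitochondrial respiratory chain were higher. Adjusted over the list alone, 10 of 18 genes of the digestive carbohydrase list fell in the additive model (limma, lowest adjusted p 0.00169). Their mean log2 changes were -3.21 to -0.78, the smallest being that of LManV, a lysosomal alpha-mannosidase gene. By the same adjustment 36 of 38 respiratory chain genes rose, by 0.26 to 0.71 (limma, lowest adjusted p 0.014). Over all 9848 genes none of them passed. Muscle genes, from a tissue rich in mitochondria, were higher in the same libraries (medians 0.43 and 1.14) and egg genes lower in females (-3.75), so a change in the share of tissues was not separated from a change within them. The carbohydrases that fell included tobi, an alpha-glucosidase under the control of insulin-like and adipokinetic signals (mean log2 change -3.21, SE 0.37), the maltase Mal-A6 (-2.11, SE 0.33) and the amylase Amy-p (-1.64, SE 0.15). tobi (3R:25344761-25346921) went from 273 FPKM on ND to 23 on HFD in males and from 59 to 7 in females. Mal-A6 went from 369 to 64 FPKM and from 114 to 34. Among respiratory chain genes, SdhB of succinate dehydrogenase went from 393 to 599 FPKM in males and from 252 to 431 in females, and ND-24 of complex I from 215 to 349 and from 159 to 262. The medians of the respiratory chain list were 0.44 in males and 0.46 in females, with 38 of 38 genes above 0 in each sex, at the 99.55 percentile of random lists in females and above all of them in males.

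Some lipases and digestive serine proteases were lower as well. Adjusted over the list alone, 4 of 12 lipases tested in both sexes fell, with CG8093 at -1.92 (SE 0.30; limma, adjusted p 0.0144) and the gut lipase magro (mag) at 137 FPKM on ND and 82 on HFD in males and at 77 and 22 in females. Another of the 4, Lip3, was at 1 FPKM on ND and a listed 0 on HFD in both sexes, a step of a single rounding unit. Of 28 serine proteases of the digestive list, Jon99Ci and Jon25Bi fell by the same adjustment (limma, adjusted p 0.00725 and 0.0197). Both belong to the Jonah family of midgut proteases. Jon99Ci (3R:29925226-29926189) was at 70 and 12 FPKM in males and 71 and 5 in females, and Jon25Bi (2L:4954279-4955144) at 132 and 33, and 531 and 30. Lipases had median changes of -0.56 in males and -0.71 in females, carbohydrases of -1.22 and -0.87, and serine proteases of -0.09 and -0.29, the latter -0.09 after median-centring. These 3 lists stood apart as lower in both sexes and the respiratory chain and muscle lists as higher, out of 26 lists measured in both. Of the 26, 20 lay outside the bounds in males and 14 in females, and 7 did so in opposite directions against 5 alike. Lists outside the bounds in both sexes were thus not mostly alike. Lipases no longer stood apart with a pseudocount of 5.

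Among single genes, 2 metallothioneins were higher and 2 storage protein genes lower in both sexes. The metallothionein MtnB (3R:20503102-20503746) rose from 99 to 448 FPKM in males and from 66 to 445 in females, a mean log2 change of 2.45 (SE 0.25, 95% interval 1.83 to 3.08; limma, adjusted over the list alone p 0.00354, over all genes 0.29). MtnE also rose by the list's adjustment (1.19; limma, adjusted p 0.0387), from 110 to 213 and from 55 to 150 FPKM, and so did the small heat shock gene Hsp22 (0.93; limma, adjusted p 0.00989), at 26 and 45 and at 31 and 67 FPKM. Genes with no function named in the tables, CG14963 (17 and 58 FPKM in males, 6 and 70 in females), CG11911 (67 and 293, 264 and 789) and CG43680 (40 and 126, 80 and 225), were also higher in both sexes. Lower in both were the larval serum protein genes Lsp2 (9 and 1, 123 and 2 FPKM) and Lsp1beta (71 and 15, 367 and 29), which encode hexamerin storage proteins of the fat body, and CG34040 (62 and 2, 11 and 1) and CG34166 (560 and 121, 241 and 11). Sodh-1, a sorbitol dehydrogenase gene, fell within the sugar metabolism list (-1.64; limma, adjusted p 0.0117), from 191 to 58 and from 23 to 7 FPKM. Of the 20 genes the rule took as changed alike in both sexes, 9 were noncoding RNAs, mostly small ones.

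Muscle genes were higher on HFD in both sexes. In the muscle list 14 of 24 genes rose when adjusted over the list alone, by 0.43 to 1.25 (limma, lowest adjusted p 0.0462). Troponin C gene TpnC4 was at 15 and 34 FPKM in males and 3 and 17 in females, the flight muscle actin Act88F at 16 and 25, and 6 and 25, and the Z-disc gene Zasp66 at 968 and 1415, and 298 and 901. The list's median was 0.43 in males and 1.14 in females, and 14 of its 24 genes were at least 2-fold higher in females. The difference between the sexes was not tested, and egg and germline genes were lower in the same female library. Neuron and photoreceptor genes were also higher in females on HFD, with 24 of 29 genes at least 2-fold higher and a median of 1.35, against 0.08 in males, a male value that turned to -0.01 when libraries were rescaled to a common sum. The rhodopsin genes ninaE (1047 and 2823 FPKM) and Rh4 (33 and 106) were among them. In males 15 photoreceptor genes, looked at apart after the values were seen, had a median of 0.37, with 13 above 0. Haemocyte genes had medians of -0.46 in males and -0.42 in females. Col4a1, a basement membrane collagen, and the prophenoloxidase PPO1 (4 and 2 FPKM in males, 4 and 1 in females) fell by the list's adjustment (-0.68 and -1.03; limma, adjusted p 0.0469 for PPO1).

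**Figure D1:**
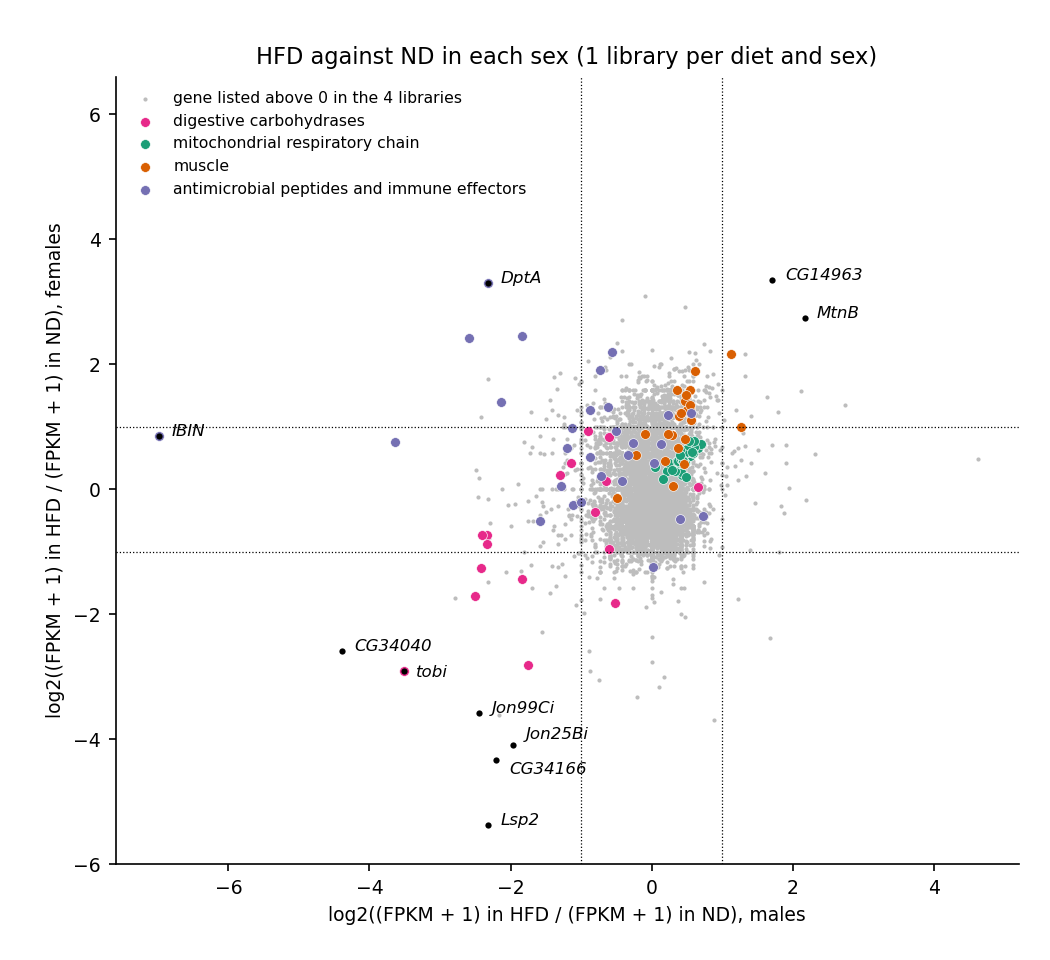
Each point is a gene listed above 0 in the 4 libraries compared, at its log2((FPKM + 1)/(FPKM + 1)) change from ND to HFD in males (x axis) and females (y axis). Genes of 4 lists are coloured, some single genes are named and dotted lines lie at 2-fold. MtnB lies at 2.17 and 2.73, tobi at -3.51 and -2.91, and IBIN at -6.98 in males and 0.86 in females.

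Egg genes were much lower in females on HFD. All 22 yolk, vitelline membrane and chorion genes measured were at least 2-fold lower than on ND, with a median log2 change of -3.75. The yolk protein genes Yp1, Yp2 and Yp3 went from 7367, 6531 and 6552 FPKM to 2385, 1189 and 1895. Chorion genes, which build the outer eggshell late in oogenesis, went from 2057 to 1 FPKM (Cp15), from 846 to 1 (Cp16), from 931 to 2 (Cp18) and from 1714 to 2 (Cp19), and Femcoat from 121 to a listed 0. In the germline and cell division list 13 of 19 genes were at least 2-fold lower in females, with a median of -1.11. They included nos, a translational repressor of germ cells (137 and 48 FPKM), the piRNA pathway gene aub (41 and 14) and stg, a cell cycle phosphatase (137 and 62). stg also fell by the list's adjustment in the additive model (limma, adjusted p 0.00987), although its male values were only 1 and 0 FPKM. The male lists had medians of 0.02 for accessory gland and 0.05 for testis genes, values that turned to -0.07 and -0.04 after rescaling to a common sum. Sfp96F, a seminal fluid gene, was at 545 FPKM on ND and 2332 on HFD.

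**Figure D2:**
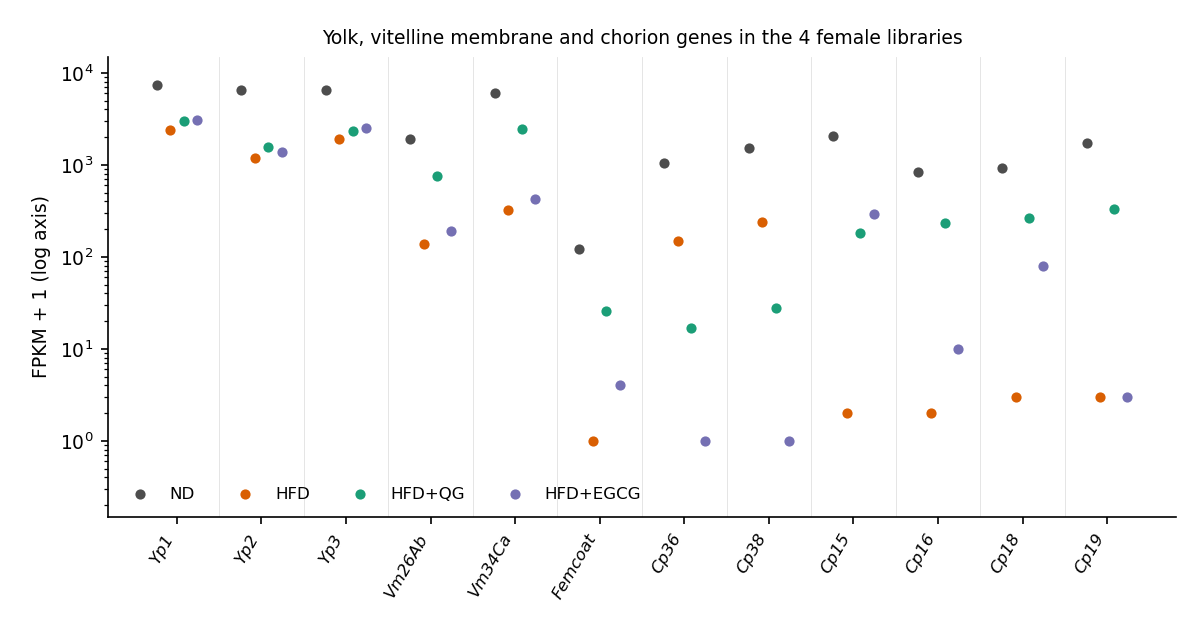
Each dot is the FPKM + 1 of an egg gene in 1 of the 4 female libraries, on a log axis. All 12 genes were highest on ND, and Cp15 was at 2057 FPKM on ND, 1 on HFD, 180 on HFD+QG and 291 on HFD+EGCG.

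Immune genes were lower in males and higher in females on HFD. Of the antimicrobial peptide and immune effector list, 16 of 37 genes were at least 2-fold lower in males and 14 of 36 at least 2-fold higher in females, with medians of -0.74 and 0.75. The Diptericin genes DptA and DptB, antibacterial peptides of the Imd pathway, were at 99 and 19, and 74 and 20 FPKM in males, and at 13 and 137, and 38 and 213 in females. IBIN, a transcript induced by infection, went from 252 to 1 FPKM in males and from 79 to 144 in females. Turandot and JAK-STAT genes had medians of -0.42 and 0.81, and TotM, a secreted stress peptide gene, went from 7 to 5 and from 13 to 90 FPKM. Fat synthesis genes had medians of -0.35 in males and 0.34 in females. FASN1, the main fatty acid synthase gene, went from 267 to 152 FPKM in males and from 108 to 153 in females, FASN2 from 76 to 92 and from 21 to 93, and ACC, the acetyl-CoA carboxylase, from 134 to 68 and from 45 to 51. No member of these 3 lists passed limma over all genes or adjusted over the list alone, which is a test of changes shared by the sexes, and the difference between the sexes itself was not tested.

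Over all genes tested, 160 were at least 2-fold higher and 293 lower on HFD in males, and 1466 higher and 514 lower in females, so that 35.3% and 74.0% of the different genes were higher. Median-centring changed these shares to 19.8% in males and 90.5% in females, and rescaling to a common sum gave 18.7% in males. The counts depended strongly on genes at low FPKM. At an FPKM of at least 10 they were 43 higher and 120 lower in males, and 561 and 151 in females. With a pseudocount of 5 they were 42 and 114, and 384 and 149. The median of all genes in females was -0.12 as deposited and 0.04 after centring. In both sexes alike 44 genes were higher and 60 lower, 104 in all against 39.1 for independent lists, while 107 were different in opposite ways against 52.0. limma passed 0 genes at an adjusted p under 0.05 (lowest 0.29), with 1336 at an unadjusted p under 0.05. limma without a trend also passed 0, with 1272. Without the male ND library limma passed 3839 genes, 1711 higher and 2128 lower (lowest adjusted p 0.0155), a fit in which ND is represented by the female library alone and that library is assumed to vary like the others.

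The second question was what QG changed on the high-fat diet. Cytochrome P450 gene Cyp6w1 (2R:6173684-6176195) was higher in both sexes, at 161 and 366 FPKM in males and 37 and 96 in females, a mean log2 change of 1.27 (SE 0.49; limma, unadjusted p 0.0456, adjusted p 1). Also higher were 5 odorant-binding or antennal genes taken by the rule as most changed, with Obp83a (3R:5972155-5975245) at 7 and 39 FPKM in males and 8 and 15 in females, Obp83b at 14 and 57, and 10 and 23, Os-C at 7 and 34, and 7 and 15, a10 at 10 and 40, and 12 and 23, and Obp28a at 6 and 18, and 5 and 12. All 5 had been lower on HFD than on ND in males, at 23, 32, 25, 30 and 9 FPKM on ND, so the male difference with QG is measured against a low HFD library. Lower in both sexes were the C-type lectin gene lectin-37Da (2L:19418317-19419029), at 71 and 21 FPKM in males and 582 and 154 in females, the serine protease gene Ser8 (13 and 8, 6 and 3) and CG7567 (27 and 15, 54 and 34). The other 11 genes that the rule took as changed alike in both sexes were noncoding RNAs.

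Part of the egg list was higher in the QG female library than in the HFD one. Of 22 genes 13 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 2.51. Cp16, Cp18 and Cp19 were at 1, 2 and 2 FPKM on HFD and 232, 266 and 334 on HFD+QG, and the vitelline membrane gene Vm34Ca at 326 and 2440, still under its 6015 on ND. Cp36 and Cp38 went the other way, from 149 to 16 and from 236 to 27. Germline genes in females had a median of 0.29, with 17 of 19 above 0. Of 26 lists, 13 lay outside the bounds of random lists in males and 10 in females, and 5 did so in opposite directions. Muscle was the list that stood apart in both sexes, at medians of -0.22 in males (-0.11 after rescaling to a common sum, under which the random lists were not rerun) and -0.14 in females, with TpnC4 at 34 and 27 FPKM and 17 and 13, and the troponin T gene up at 958 and 828, and 681 and 575.

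Digestive protease and immune genes had medians of opposite sign in males and females, a difference that was not tested. In males 27 of 28 digestive serine proteases were below 0 (median -0.45), with Jon99Cii at 373 FPKM on HFD and 175 on HFD+QG, while in females the median was 0.06 and Jon99Cii was at 192 and 358. Fat synthesis genes had a median of 0.13 in males, with FASN1 at 152 and 236, ACC at 68 and 97, and AcCoAS, an acetyl-CoA synthase gene, at 119 and 160 FPKM. In females the median was 0.05 and FASN1 was at 153 and 155. Immune effectors had medians of 0.67 in males and -0.31 in females. DptB was at 20 and 101 FPKM in males and at 213 and 34 in females, and TotA at 26 and 87, and 180 and 126. Lysozyme gene LysX was at 3 FPKM and a listed 0 in males and 19 and 3 in females. No member of any list passed limma adjusted over the list alone (lowest adjusted p 0.149).

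In total 130 genes were at least 2-fold higher and 137 lower in males with QG, and 192 and 225 in females. At an FPKM of at least 10 the numbers were 39 and 31, and 24 and 42. The share higher in males, 48.7%, became 73.1% after rescaling to a common sum and 70.7% after median-centring. Both sexes shared 24 higher and 22 lower genes, and 47 were different in opposite ways. limma passed 0 genes (lowest adjusted p 1), with 107 at an unadjusted p under 0.05, and without a trend 0 and 133. Disagreement between the sexes on ND enters the error of this fit, so it could miss changes with QG. Cyp4g1, the oenocyte enzyme that makes cuticular hydrocarbons, was listed at 0 in the QG and EGCG male libraries against 9209 FPKM on ND and 9726 on HFD. It lies at X:467057-469335 in a run of 20 overlapping genes (X:268509-470726), of which all 8 that were above 0 in both the male ND and HFD libraries were listed at 0 in both male supplement libraries, ewg (12, 10, 0 and 0 FPKM) and CG12470 (73, 78, 0 and 0) among them. The genes on either side, CG13377 (6, 6, 6 and 7) and ebo (10, 9, 10 and 10), were not. In females Cyp4g1 was at 2251, 6529, 7322 and 6747 FPKM.

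**Figure D3:**
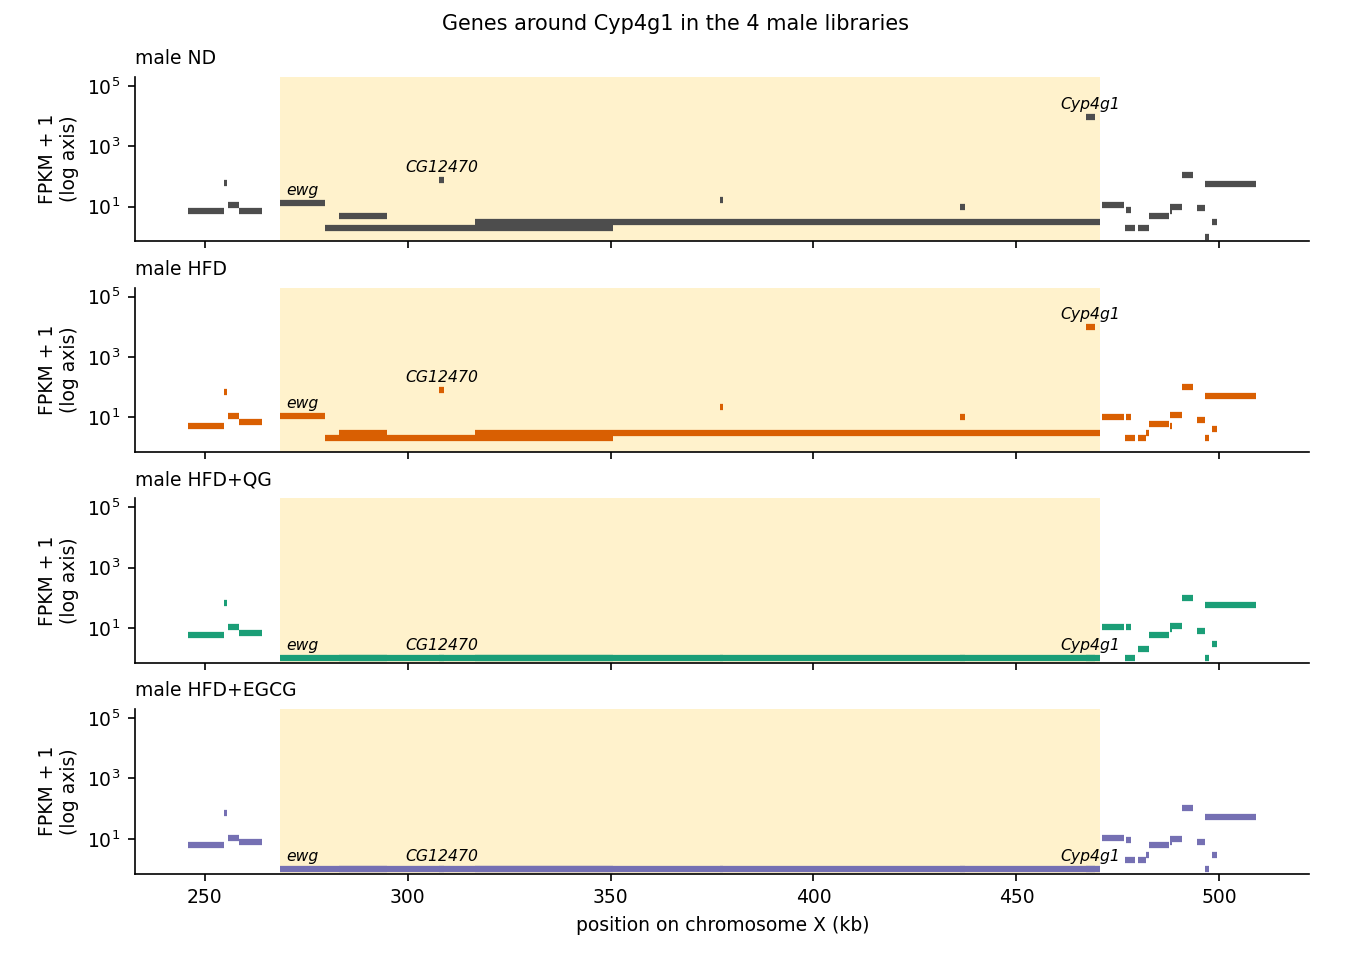
Bars are the genes around Cyp4g1 at their position on chromosome X (kb) and their FPKM + 1 on a log axis in the 4 male libraries, where a bar at 1 is a gene listed at 0 and the shaded span is the run of overlapping genes. Cyp4g1 was at 9209, 9726, 0 and 0 FPKM on ND, HFD, HFD+QG and HFD+EGCG.

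The third question was what EGCG changed. The P450 genes Cyp6a21, Cyp6a8 and Cyp6w1 were higher in both sexes, while the P450 list as a whole had medians of 0.00 in males and 0.07 in females and none of its members passed limma. Cyp6a21 (2R:14885264-14886947) was at 20 and 52 FPKM in males and 67 and 154 in females (mean log2 change 1.26, 95% interval 0.27 to 2.26), and its neighbour Cyp6a8 (2R:14887171-14889010), which hydroxylates fatty acids, at 14 and 29, and 3 and 19 (1.66, 0.25 to 3.07). Cyp6w1 was at 161 and 217, and 37 and 192 FPKM (1.39, 0.16 to 2.62). Maltase gene Mal-B1 was higher in both sexes, at 20 and 52, and 2 and 5 FPKM (1.17, 0.31 to 2.02), still under its ND values of 70 and 20. Also higher in both were the cold-responsive gene Frost (Fst), at 11 and 27, and 15 and 34, and CG32198, at 16 and 82, and 19 and 39. Lower in both sexes were fit, a fat body gene for a protein that signals satiety (7 and 3, 161 and 106 FPKM), the Attacin gene AttA (9 and 5, 18 and 9) and ND-AGGG of complex I, at 122 and 8 FPKM in males and 6 and 3 in females. ND-AGGG was at 4 to 8 FPKM in the other 3 male libraries. Here 12 of the 20 genes the rule took were noncoding RNAs.

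Beta-oxidation genes were the list that stood apart as higher in both sexes with EGCG. Of 26 lists, 11 lay outside the bounds of random lists in males and 10 in females, and 1 did so in opposite directions. The medians were 0.06 in males and 0.10 in females, with 12 of 18 and 16 of 18 genes above 0, and the peroxisomal acyl-CoA oxidase gene Acox57D-p was at 26 and 34, and 51 and 64 FPKM. In males 16 of 18 digestive carbohydrases were above 0 (median 0.57), with Mal-A1 at 182 and 458 FPKM and tobi at 23 and 47, while the female median was 0.00 and Mal-A1 was at 173 and 114. Glutathione S-transferases and UGTs had a male median of 0.10, and GstD2 was at 6 and 21 FPKM. Ribosomal protein genes had a male median of 0.12, with 81 of 88 above 0. Testis genes were below 0 in 20 of 20 cases in males (median -0.51), among them ocn at 419 and 227 FPKM, and accessory gland genes had a median of -0.27. Egg genes in females had a median of 0.33, with 4 at least 2-fold higher, Cp15 at 1 and 291 among them, and 7 at least 2-fold lower, 6 of which were listed at 0 with EGCG, and Cp36 and Cp38 went from 149 and 236 FPKM to a listed 0. Heat shock genes in females had a median of -0.21.

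With EGCG 176 genes were at least 2-fold higher and 135 lower in males, and 178 and 234 in females. The male share of higher genes, 56.6%, became 78.5% after rescaling to a common sum and 78.3% after median-centring. Alike in both sexes were 25 higher and 20 lower genes, and 54 were different in opposite ways. limma passed 0 genes (lowest adjusted p 0.222), with 102 at an unadjusted p under 0.05, and without a trend 0 and 131. The limit on the error given for QG applies here too. Adjusted over the list alone, 0 members of any list passed (limma, lowest adjusted p 0.151).

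**Figure D4:**
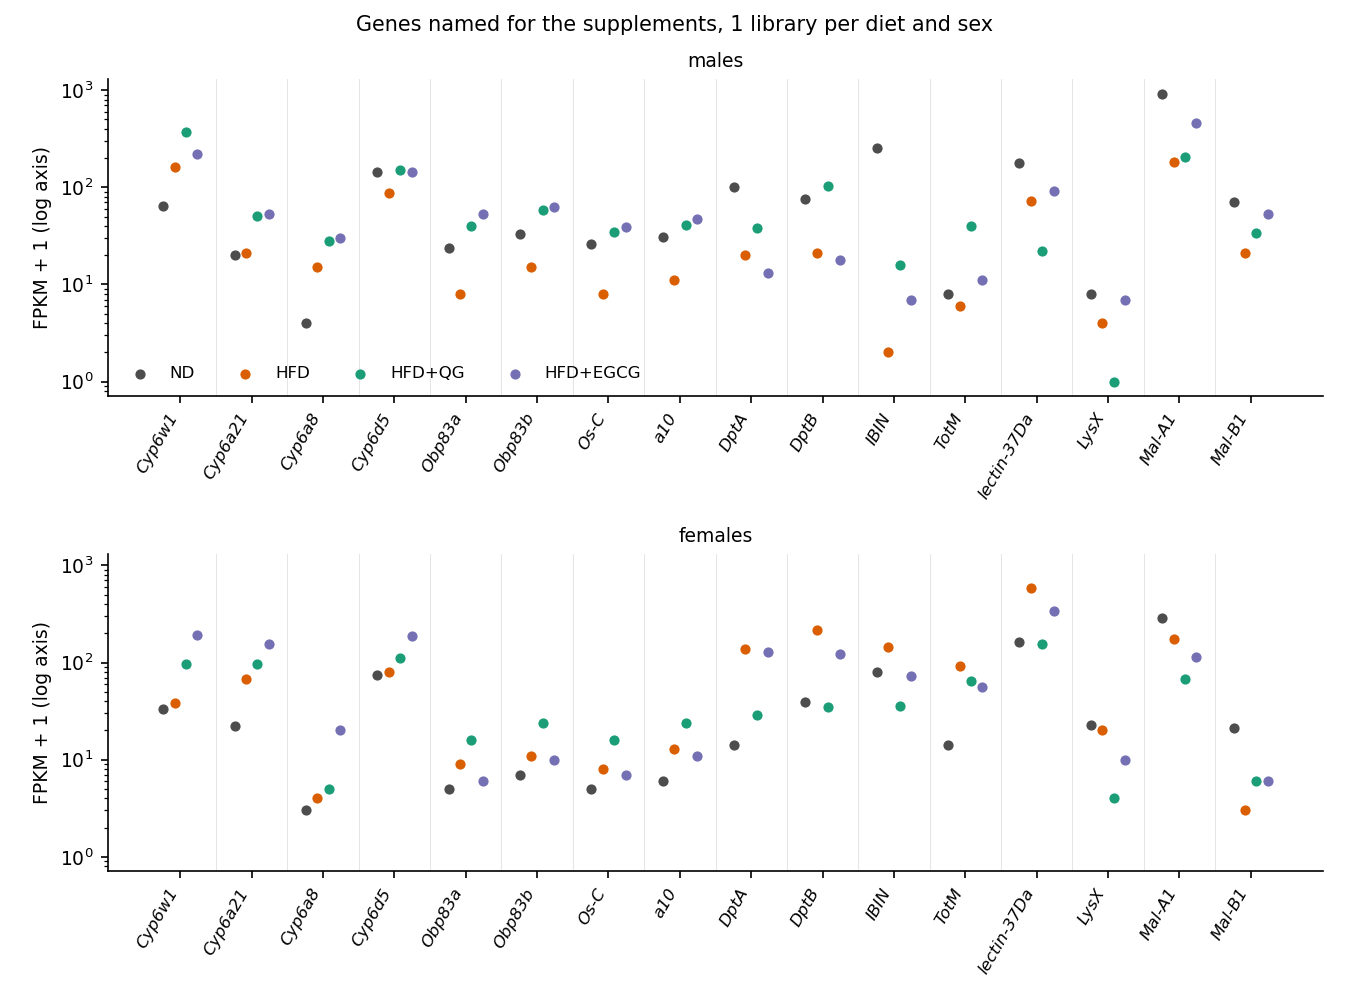
Each dot is the FPKM + 1 of a gene, on a log axis, in 1 of the 8 libraries, with males and females in separate panels. Cyp6w1 was at 161, 366 and 217 FPKM in males and at 37, 96 and 192 in females on HFD, HFD+QG and HFD+EGCG.

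The compounds were then compared with each other. QG and EGCG are different flavonoids, a flavonol glucoside and a galloylated flavanol, and their doses are not given, so the comparison is of the diets as fed. LysX (3L:1194739-1195302) was lower with QG than with EGCG, at 0 and 6 FPKM in males and 3 and 9 in females (limma, unadjusted p 0.00505, adjusted p 1). lectin-37Da was at 21 and 90, and 154 and 337 FPKM, with a difference of -1.59 (-3.55 to 0.38). For the P450 genes higher with both, the differences were -0.12 for Cyp6w1 (-1.35 to 1.11), -0.37 for Cyp6a21 (-1.37 to 0.62) and -1.05 for Cyp6a8 (-2.46 to 0.36), and for the maltases -0.96 for Mal-A1 (-2.14 to 0.22) and -0.32 for Mal-B1 (-1.18 to 0.54). P450s as a list were lower with QG than with EGCG, at medians of -0.04 in males and -0.09 in females, the former 0.00 after rescaling to a common sum. Glutathione S-transferases and UGTs had medians of -0.05 and -0.03, and the male one turned to 0.01 after the same rescaling. In females 17 of 22 egg genes were at least 2-fold higher with QG (median 2.37), with Vm34Ca at 2440 and 426 FPKM and Vm26Ab at 763 and 189. Of these 17 genes, 6 were listed at 0 with EGCG. Testis genes were higher with QG in males (median 0.32).

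Between the compounds 113 genes were at least 2-fold higher with QG and 157 lower in males, and 208 and 168 in females, with 20 higher and 20 lower in both sexes and 47 in opposite ways. limma passed 0 genes (lowest adjusted p 0.222), with 83 at an unadjusted p under 0.05, and without a trend 0 and 102. The 95% interval of the difference lay within 2-fold for 8097 of 9848 genes (82.2%), with a median half-width of 0.54 log2, and it excluded 0 for 83. Among 5169 genes at an FPKM of at least 10 in every library it lay within 2-fold for 4887 (94.5%). The error behind these p-values and intervals is shared by all diets, ND included. A p that misses the threshold does not show that the compounds act alike. Within a sex the changes from HFD to QG and to EGCG correlated across genes at a Spearman rho of 0.51 in males and 0.60 in females, but both share the HFD library, and unchanged groups simulated with that sharing gave 0.46 in each sex. The covariances were 0.0935 and 0.0788 against simulated values of 0.068 and 0.0621. The male value includes Cyp4g1 and a small noncoding RNA, at 9726 and 764 FPKM on HFD and listed at 0 in both male supplement libraries. It was not computed without them, so a male excess cannot be read from it. Genes at least 2-fold different with both compounds in the same direction numbered 76 higher and 69 lower in males. The simulation gave 69.1 for both directions together, and independent lists 2.3 and 1.9. In females they numbered 86 and 123, against 68.6 simulated for both directions together and 3.5 and 5.3 for independent lists. The observed numbers were above the simulated total in each sex, but this comparison cannot show an excess. Simulated values were not rounded to whole FPKM, whereas in the data a step from 0 to 1 FPKM counts as 2-fold. The simulated noise was set from the difference between the QG and EGCG libraries of a sex. The HFD library cannot be split, so part of any excess may come from sharing it. Across the sexes, where no library is shared, rho was 0.06 and -0.08. Genes are not independent replicates in any of these correlations.

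**Figure D5:**
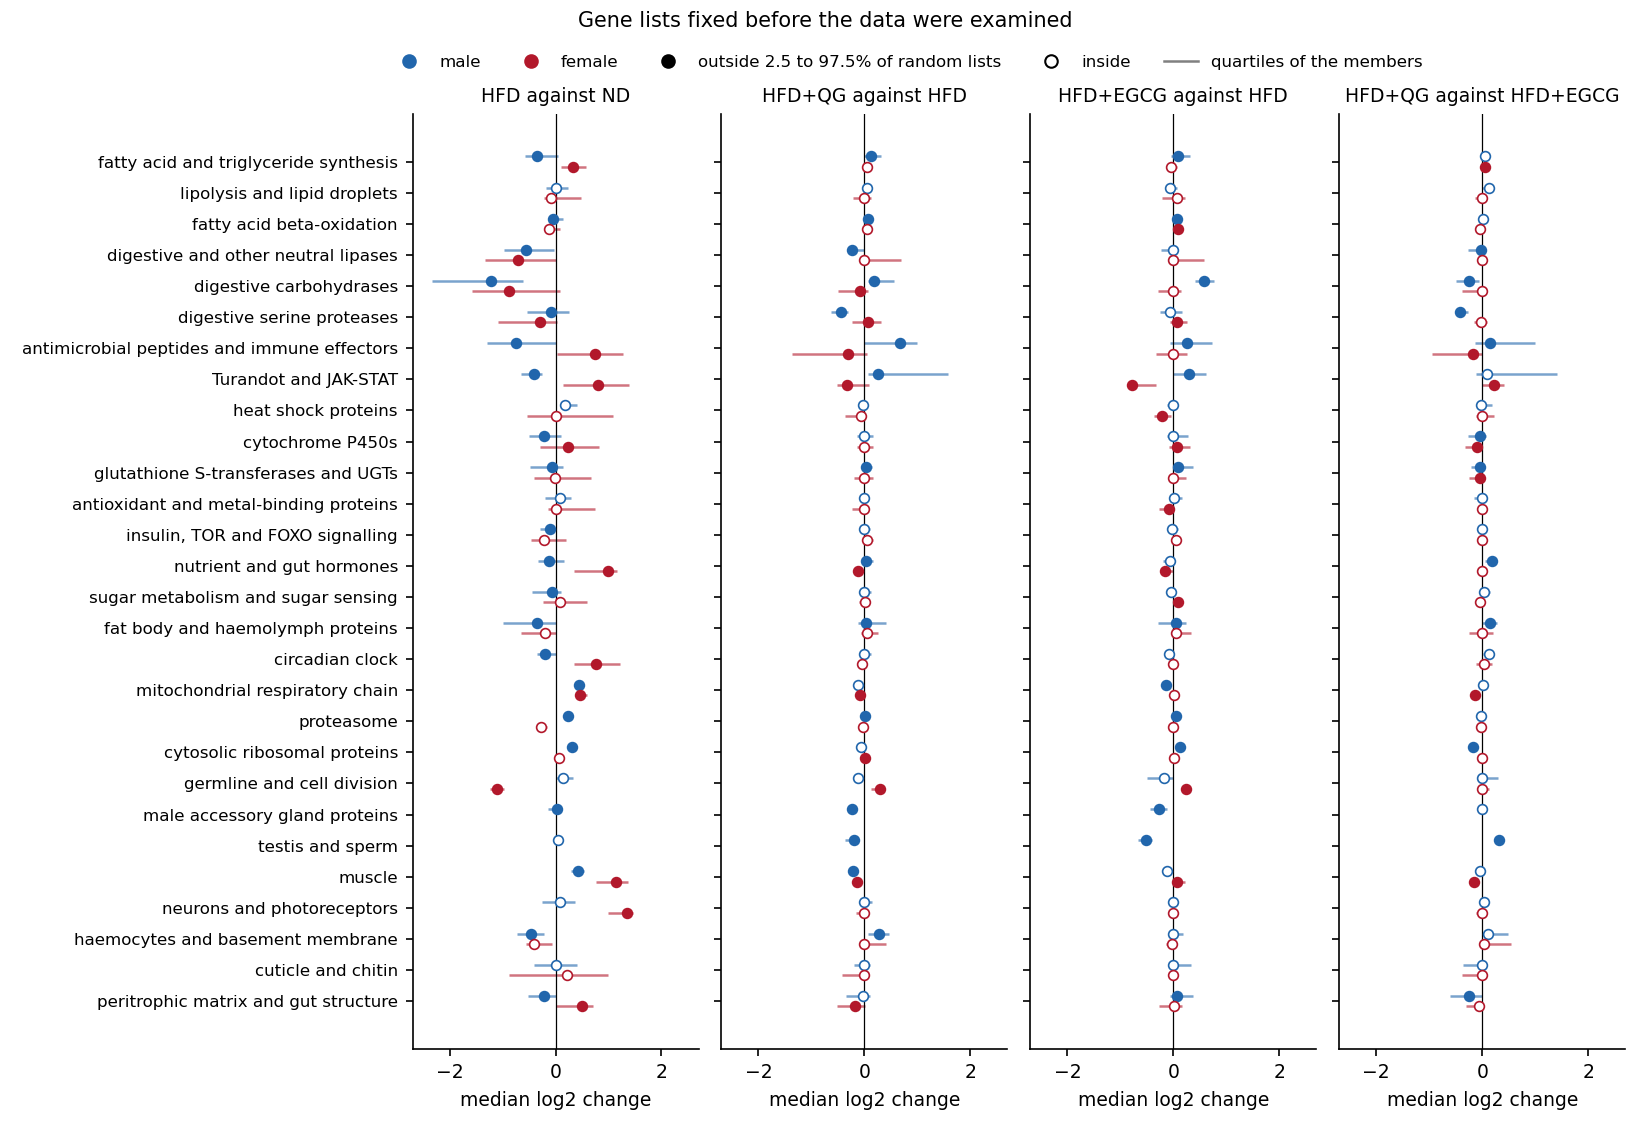
Dots are the median log2 changes of 28 gene lists and lines their quartiles, in males and females for each comparison; the egg list, at -3.75, 2.51, 0.33 and 2.37 in females, is left out for scale. From ND to HFD the respiratory chain list lay at 0.44 and 0.46 and the carbohydrases at -1.22 and -0.87.

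The last question was whether the supplements moved the genes changed by the high-fat diet back towards ND. Taken in the other sex, where no library is shared, genes higher on HFD had a median change of 0.00 with each compound, and so did genes lower on HFD, values set largely by ties among low rounded FPKM. A return towards ND can be read in the other sex only for genes that HFD changed alike in both. At 2-fold, 104 genes changed alike and 107 in opposite ways, and 42 and 30 at an FPKM of at least 10. Values across the sexes therefore cannot decide the question. At an FPKM of at least 10, genes lower on HFD in males had medians of -0.27 with QG and -0.14 with EGCG in females. Of these genes, 64.2% and 57.5% were lower in females with the compound than on HFD alone. Genes lower on HFD in females had medians of -0.03 and -0.13 in males. Genes higher on HFD had medians of -0.18 and -0.02 in females and -0.03 and 0.00 in males. In the same sex 7 of the 8 medians had the opposite sign to the change on HFD and 1 was 0.00. With QG they were -0.32 and 0.14 in males for genes higher and lower on HFD, and -0.09 and 0.30 in females, and with EGCG -0.42 and 0.47 in males and 0.00 and 0.26 in females. The shared HFD library alone gives such a sign. Across genes, the HFD change and the supplement change in the same sex correlated at rho -0.36 in males and -0.55 in females for QG and -0.29 and -0.46 for EGCG, while simulated unchanged groups gave -0.47 and -0.45. The covariances were -0.0653 and -0.1242 for QG and -0.0943 and -0.109 for EGCG, against simulated values of -0.0684 and -0.0621. The male EGCG value includes mt:CoI, at 11765 FPKM on ND, a listed 0 on HFD and 15199 on HFD+EGCG. It was not computed without that gene. The limits of the simulation given for the comparison of the compounds apply here too. Across sexes rho lay at -0.04 and -0.02 for QG and at 0.00 and 0.10 for EGCG. MtnB, tobi and Jon99Ci stayed on the HFD side of ND in all 4 supplement libraries, with MtnB at 204 to 451 FPKM, tobi at 4 to 47 and Jon99Ci at 4 to 12. This does not exclude a partial return. With QG and EGCG, MtnB was at 204 and 227 FPKM in females against 445 on HFD and 66 on ND. In males MtnB was at 367 and 451 against 448 on HFD. For tobi the values were 36 and 47 against 23 on HFD in males, and 4 and 5 against 7 in females. Diet profiles of males and females did not match better than chance matchings, with a mean Spearman rho of 0.02 (one-sided exact permutation test over 24 matchings, p 0.3333; highest of the other matchings 0.06).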

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

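The tests of library scaling, of other tissues' lists, of photoreceptor genes and of the run of overlapping genes were chosen only after the result was seen. Several gene lists stood out because their medians lay on opposite sides of 0 in males and females and outside the percentile bounds of random lists in each sex. These differences were not tested, since each diet has 1 library per sex.

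From ND to HFD, immune effectors had medians of -0.74 in males and 0.75 in females, a female minus male difference of 1.48. Turandot and JAK-STAT genes differed by 1.22 (-0.42 and 0.81), nutrient and gut hormone genes by 1.12 (-0.12 and 1.00), clock genes by 0.96 (-0.19 and 0.77), peritrophic matrix genes by 0.70 (-0.21 and 0.49, with a female percentile of 97.54, and inside the bounds after median-centring), fat synthesis genes by 0.68 (-0.35 and 0.34) and P450s by 0.46 (-0.22 and 0.23). Among their members, the immune gene edin was at 11 and 1 FPKM in males and at 2 and 15 in females, and the interferon-like Vago at 29 and 18, and 24 and 64.

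From HFD to HFD+QG, immune effectors differed by -0.98 (0.67 in males and -0.31 in females), Turandot and JAK-STAT genes by -0.58 (0.26 and -0.32), digestive serine proteases by 0.51 (-0.45 and 0.06), carbohydrases by -0.26 (0.18 and -0.08) and hormone genes by -0.15 (0.04 and -0.12). From HFD to HFD+EGCG, Turandot and JAK-STAT genes differed by -1.08 (0.29 and -0.79). Between QG and EGCG, immune effectors differed by -0.30 (0.14 and -0.17). TotM was at 5, 39 and 10 FPKM in males and 90, 64 and 55 in females on HFD, HFD+QG and HFD+EGCG.

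Female HFD flies had 1466 genes at least 2-fold higher and 514 lower than ND flies. At an FPKM of at least 10 the numbers were 561 and 151. The authors' scaling does not account for the excess of higher genes, since the share higher went up to 90.5% after median-centring. A smaller share of ovary RNA could account for part of it. Female-biased genes had a median of -0.69 in females and 0.00 in males, male-biased genes 0.64 in females, and muscle and neuron lists were higher. Less ovary RNA does not explain every female change, because digestive carbohydrases, which are not ovary genes, had a median of -0.87. These lower genes cannot show whether less ovary RNA is the whole cause of the excess of higher genes. A response of egg production to the diet stays open and was not tested.

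The antennal genes Obp83a, Obp83b, Os-C, a10 and Obp28a were lower in the male HFD library than in the other 3 male libraries. A smaller amount of antennal tissue in that library could explain it, since 7 antennal genes other than those named had a median of -0.58 from ND to HFD, but 5 of the 7 were below 0, several at low FPKM (lush at 2 and 1, Obp69a at 4 and 2), while the more abundant Obp19d (785 and 839) and antdh (18 and 20) were above 0. A smaller amount of head tissue does not, because 15 photoreceptor genes had a median of 0.37 in males. With QG and EGCG the male antennal medians were 1.22 and 1.42 against the same HFD library, so that library may account for the male difference. The 5 named genes were also higher with QG in females (Obp83b at 10 and 23, Os-C at 7 and 15). The rule took them for rising in both sexes, so this cannot count against that explanation. With EGCG they were not higher in females (Obp83b at 10 and 9, Os-C at 7 and 6). In females 3 other antennal genes had medians of 0.18 with QG and 0.01 with EGCG, with 1 below 0 in each case. A response of antennal genes to the diet stays open and was not tested.

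Some of the most abundant genes were listed at 0 in single libraries. mt:CoI, the mitochondrial cytochrome oxidase subunit I, was listed at 11765, 0, 0 and 15199 FPKM in males on ND, HFD, HFD+QG and HFD+EGCG, but less mitochondrial RNA does not explain it, since 11 other mitochondrial protein-coding genes were all above 0 with a median of 0.45 from ND to HFD. For Cyp4g1, fewer oenocytes do not explain it, because the lower of the medians of 7 other oenocyte genes with the supplements was 0.046. Failure of the whole locus within 20 kb could not be judged, with 0 genes eligible, but in the run of overlapping genes that holds Cyp4g1 8 of 8 genes above 0 in the male ND and HFD libraries were at 0 in both male supplement libraries, which is consistent with a failed estimate of that run by the authors' software. A diet effect on Cyp4g1 itself was not tested and the zeros were not read as loss of expression.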

How the results depend on the processing

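Leaving out genes listed at 0 and keeping protein-coding genes only were chosen only after the result was seen. Single named genes were checked only with a pseudocount of 0.1 and after median-centring. No named change of at least 2-fold reversed in either. After median-centring 33 of 1042 named changes crossed 2-fold or, where smaller, changed sign, while 0 did with a pseudocount of 0.1. The numbers of genes 2-fold different in both sexes depended on the size rule and on the handling of genes at low FPKM. For HFD against ND the 104 genes became 38 with a pseudocount of 5, 42 at an FPKM of at least 10, 64 after median-centring, 376 with a 1.5-fold rule and 48 without genes listed at 0. For QG against HFD the 46 became 2, 10, 29, 119 and 10, and 19 with protein-coding genes only. For EGCG against HFD the 45 became 7, 10, 113 and 10 under the same settings other than centring, and 18 with protein-coding genes. For QG against EGCG the 40 became 7, 9, 104 and 7, and 13 with protein-coding genes. Fewer genes are tested in the filtered sets, and the cause of the shift by centring was not tested. limma passed 0 genes in 71 of 72 alternative fits of the 4 planned comparisons, 4 of which, with no FPKM minimum, test the same genes and check nothing. The range for HFD against ND was 0 to 3839, the latter without the male ND library, where the cause was not tested. The unplanned comparisons of HFD+QG and HFD+EGCG with ND passed 0 genes in the fit to all libraries and 3169 and 3545 without the male ND library (limma). Genes 2-fold different on HFD in one sex were followed in the other sex, and a gene different in both sexes counts in each. Of 1709 such cases not tied at 0 with QG, 52.3% went the opposite way. This became 49.3% with a pseudocount of 5, 43.5% after rescaling to a common sum and 42.2% after centring. For EGCG 48.5% of 1741 cases became 41.1%, 44.3% at an FPKM of at least 10, 42.1% and 40.2%, and the cause was not tested. Genes are not independent replicates, so these percentages carry no interval. Lists apart in both sexes with EGCG went from 1 to 2 after centring, with P450s added as higher. Between QG and EGCG they went from 2 to 3 with a pseudocount of 5, with gut structure genes added as lower with QG. The match of diet profiles kept an exact permutation p of 0.125 to 0.3333. Rounding to whole FPKM limits what can be said of genes under about 5 FPKM.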

Other observations

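The values of Cp36, Cp38 and the other zeros were looked at only after the result was seen, without a test. Some biology of the high-fat diet lay outside the main lists. The P450 genes Cyp309a1 (34 and 6 FPKM in males, 13 and 4 in females) and Cyp9b2 (117 and 57, 208 and 102) were lower on HFD in both sexes. The iron transporter transferrin, Tsf1, was at 743 and 252 FPKM in males and 290 and 251 in females. The clock list had medians of opposite sign in the sexes, a difference that was not tested. The light-sensitive clock protein gene tim was at 129 and 76 FPKM in males and 25 and 42 in females. Pdp1, a clock transcription factor gene, was at 109 and 87, and 17 and 43. Of the peptide hormone genes, leucokinin (Lk), which acts on diuresis and feeding, was at 17 and 22, and 6 and 20, and CCHa1 at 8 and 6, and 15 and 6. Mur29B of the gut structure list was at 63 and 47, and 39 and 185, and the sterol-binding gene Npc2e at 36 and 19, and 167 and 318. The cuticle gene Cpr72Ec was at 12 and 97 FPKM in females.

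Ribosomal protein genes had a male median of 0.30, with 87 of 88 above 0, and proteasome genes 0.23, with 31 of 31 above 0, while the female medians were 0.07 and -0.27. Median-centring gave 0.25 in males and 0.26 in females for ribosomal genes and -0.07 in females for the proteasome, and rescaling to a common sum gave 0.14 in males for the proteasome, so a contrast between the sexes depends on the scaling. RpS5b, the ribosomal protein gene of the female germline, was at 611 and 260 FPKM in females. Insulin, TOR and FOXO signalling genes had medians of -0.10 and -0.22 (female -0.03 after centring) and heat shock genes 0.18 and 0.00 (female 0.20 after centring). Thor, the translation inhibitor 4E-BP, was at 708 and 549 FPKM in males and at 232 and 717 in females. Hsp26 was at 64 and 70 FPKM in males and 535 and 241 in females. Lipid turnover lists had medians of 0.00 in males and -0.08 in females for lipolysis, the latter 0.11 after centring, and of -0.05 and -0.13 for beta-oxidation, the latter 0.07 after centring. Single lipolysis genes went both ways in females. The lipid droplet gene Jabba was at 72 and 68, and 390 and 209 FPKM, and CG1882, related to the lipase cofactor CGI-58, at 103 and 123, and 66 and 126. Sugar metabolism genes had medians of -0.07 and 0.09 (female 0.28 after centring), fat body proteins -0.35 and -0.21 (female -0.01 after centring), antioxidant genes 0.08 (-0.01 after rescaling to a common sum) and 0.00, glutathione S-transferases and UGTs -0.07 and -0.02 (0.12 after centring) and cuticle genes 0.00 and 0.22.

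Genes at an FPKM of at least 100 in one library and listed at 0 in another of the same sex numbered 3 in males, mt:CoI and Cyp4g1 among them, and 10 in females. In females Cp36 was at 1041, 149, 16 and 0 FPKM and Cp38 at 1517, 236, 27 and 0 on ND, HFD, HFD+QG and HFD+EGCG. IM14, an immune-induced peptide gene, was at 0, 0, 0 and 31 in males, and in females CG13427 was at 18, 32, 0 and 0 and CG13114 at 88, 14, 0 and 0.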
